A study of Homo sapiens with 2 samples.

How the data were processed

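Total RNA from 786-O cells, an established human clear cell renal carcinoma line, was measured by sequencing of RNA libraries in 2 samples, 1 grown in medium with 25 mM glucose and 1 in medium with 0 mM glucose. The group of each sample was taken from its title. Each sample also had a short description, LucF with glucose and LucG without, whose meaning is not given in the sources used here and which was not used, so that a further difference between the cultures that it could mark is open. RNA was extracted with Trizol, per the labels' protocols. The time without glucose, the library preparation, the aligner, the counting program, the use of strand and the read length are not given in the sources used here. The genome build was hg19, per the submitters' processing notes.

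Each deposited table held 24364 rows, 1 per gene model, with the chromosome, strand, start, end, length, exon number, RefSeq transcripts, a raw count and an RPKM. The deposited counts were whole numbers without normalization, per the file headers and the values. The deposited RPKM values, reads per kilobase of gene model and per 1e6 reads, per the file headers, were the counts divided by the length and by 1 constant per library, 27.1 with glucose and 31.0 without in units of 1e6 reads. The summed counts came to 100.9% and 101.0% of these constants. RPKM values were used for this check alone, and all comparisons used the counts. The start of a gene is given as in the tables, and for each of the 3553 rows with 1 exon the stated length equalled the end minus the start. Gene models on haplotype and unplaced contigs took 1284 rows, and those on haplotype contigs had no count in either library. Rows that repeated the place and both counts of a row with another symbol (528) were dropped, and counts were summed by symbol, which left 22595 symbols. No mitochondrial-genome gene was among them. Symbols were kept as the tables give them, so that PKM2 stands for PKM and C7orf40 for SNHG15.

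Counts were read in with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). Effective library sizes were computed by the TMM method of edgeR 4.0.16 in R 4.3.3, with factors of 1.02 with glucose and 0.981 without, and CPM values are counts per 1e6 of the effective library size. A gene was called measured with at least 20 counts over both libraries, which held for 14240 symbols. For each, the ratio of the library without glucose to the library with glucose was given on the log2 scale without pseudocount, and a count of 0 was set to a floor of 3 counts (0.108 CPM with glucose, 0.0976 CPM without), which makes the ratio a bound. Its exact 95% Clopper-Pearson interval was taken from the share of the gene's counts that fell in each library. These intervals and floors cover counting error only, since reads copied by PCR are not independent molecules. With 1 library per group no test was made, no p-value is given, and a rule of size was used in its place. A gene was counted as higher without glucose when its interval lay wholly above 2-fold, and as lower when it lay wholly below 0.5-fold. The half-width of the log2 interval was about 1.42 for a gene with 20 counts over both libraries and 0.60 with 100 counts, and the median measured gene had 1480 counts.

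A set of 37 gene lists, the rule of size, the rule for named genes and the alternative settings of the next paragraph, except where stated, were fixed before the data were examined. The lists covered stress responses, amino acid, glucose and lipid metabolism, hypoxia, redox genes, autophagy, inflammation and interferon, the cell cycle, p53, apoptosis, heat shock, ribosomes, extracellular matrix, renal markers, markers of other cell types, checks of RNA selection and reference genes. Of their 791 distinct genes, 775 were matched to the tables by symbol, RefSeq accession or older symbol. The median log2 ratio of the measured members of each list was set against 10000 random lists of the same size matched on mean expression in 20 bins, and a list was called above or below the random lists when its median lay outside their central 95%. Lists with fewer than 5 measured members were given as values. These percentiles describe the 2 libraries and are not a test of the conditions. The genes named were, among genes with at least 10 CPM in either library, the 12 with the highest lower interval bound and the 12 with the lowest upper bound, up to 4 members of each list with the largest absolute log2 ratio, a fixed set of 13 genes, and the 5 genes with the most counts in each library. Other genes are named where a small count is spelled out, and were chosen after their values were seen.

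The procedure was tested on simulated data with the same 14240 genes and library sizes. Of 198 genes given a known change, all with a 4-fold or 8-fold change and none with a 1.5-fold or 2-fold change passed the rule, as did 0 unchanged genes, and 95.4% of the intervals held the true ratio. Of 100 simulated lists without a shift, 8% fell outside the central range, and of 100 lists shifted by 0.3 on the log2 scale, 100% did. Apart from the known changes, the simulated genes varied by counting error only, far less than the real genes. For the real list of 25 immediate-early genes the random range was -0.336 to 0.310. The 100% is therefore not the share of real lists with such a shift that would be found. The alternative settings were scaling by total counts, by DESeq2 1.42.0 size factors and by the upper quartile, other count minimums, other sizes for the rule, thinning of the deeper library in 20 draws, the 10 most counted genes left out of the scaling, the mean of list members and 1 CPM added to both libraries. Settings chosen after seeing the data left out small RNA genes, removed the trend with gene length, or matched random lists on length and GC content. GC content was taken from GRCh38 transcript sequences by RefSeq accession for 95.7% of the measured genes.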

Results

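The data comprised 2 RNA-seq libraries from 786-O cells, a human clear cell renal carcinoma line that lacks functional VHL, the ubiquitin ligase subunit that marks HIF proteins for degradation. One culture was grown with 25 mM glucose and the other with 0 mM glucose, to profile expression under glucose starvation. The library with glucose held 27317598 counts and the library without glucose 31345853, and 19403 and 19385 genes had at least 1 count. There were no replicates, so no difference given here has a replicate check, and higher and lower refer to these libraries rather than to the conditions. The CPM values of the 14240 measured genes had a Spearman correlation of 0.952 across genes, which are not independent replicates.

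The library without glucose had more transcripts of endoplasmic reticulum (ER) chaperones and integrated stress response genes, and fewer transcripts of histones and of replication, mitosis, lipid synthesis and interferon-stimulated genes. HSPA5, the major ER chaperone (BiP), stood at 756 CPM with glucose and 10092 CPM without, a 13.3-fold difference (95% counting interval 13.2 to 13.5), and was among the 5 most counted genes without glucose. DDIT3, which encodes the stress-induced transcription factor CHOP, was 18.3-fold higher at 342 CPM (interval 16.8 to 20.1). MKI67, the proliferation marker Ki-67, was 5.63-fold lower without glucose, at 114 CPM against 642 CPM (interval 5.43 to 5.84). TXNIP, an arrestin-like protein whose transcription follows glucose supply through MondoA, was 12.9-fold lower, at 1.07 CPM against 13.9 CPM.

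By the rule of size, 534 of the 14240 measured genes were higher and 883 were lower in the library without glucose, and 12823 passed neither bound. The median log2 ratio was 0.01 with quartiles at -0.45 and 0.42. Among genes with at least 10 CPM in either library, the leading higher genes were HSPA6, KRT17, MMP3, ATP6V0D2, DDIT3, HSPA5, C9orf150, PPP1R15A, RASGEF1B, GPR1, RAB39B and ZFAND2A. HSPA6, a strictly inducible HSP70, had 0 counts with glucose and 685 without, 207-fold more when the 0 was set to the floor of 3 counts, and at least 168-fold higher by the lower bound of its counting interval. KRT17, a keratin of basal epithelia, had a log2 ratio of 5.32 and the matrix metalloproteinase gene MMP3 one of 5.26. The leading lower genes were KCNJ16, CDH6 and 10 histone genes. The potassium channel gene KCNJ16 had 22.7 CPM with glucose and 0.618 CPM without (log2 ratio -5.20), and CDH6, a cadherin of the renal tubule, 192 and 8.36 CPM (-4.52). FN1, MALAT1 and VIM were among the 5 most counted genes in both libraries, joined by AHNAK and PKM2 with glucose and by HSPA5 and CALR without. FN1, fibronectin, had 28528 and 29292 CPM. Ratios of genes near the floor in either library depended on the scale, and with 1 CPM added to both libraries the log2 ratio was 4.54 for HSPA6, 3.44 for MMP3 and -3.87 for KCNJ16. Among genes of the lists it was then -2.84 for TXNIP, -2.47 for CCL2, 2.73 for HSPA1A, 0.996 for CRYAB, 2.47 for DERL3, 2.49 for FOS, -1.40 for IFI44L, 1.38 for ANGPTL4, 1.63 for AKR1C1, -3.70 for HIST1H3A and -2.61 for E2F2.

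**Figure D1:**
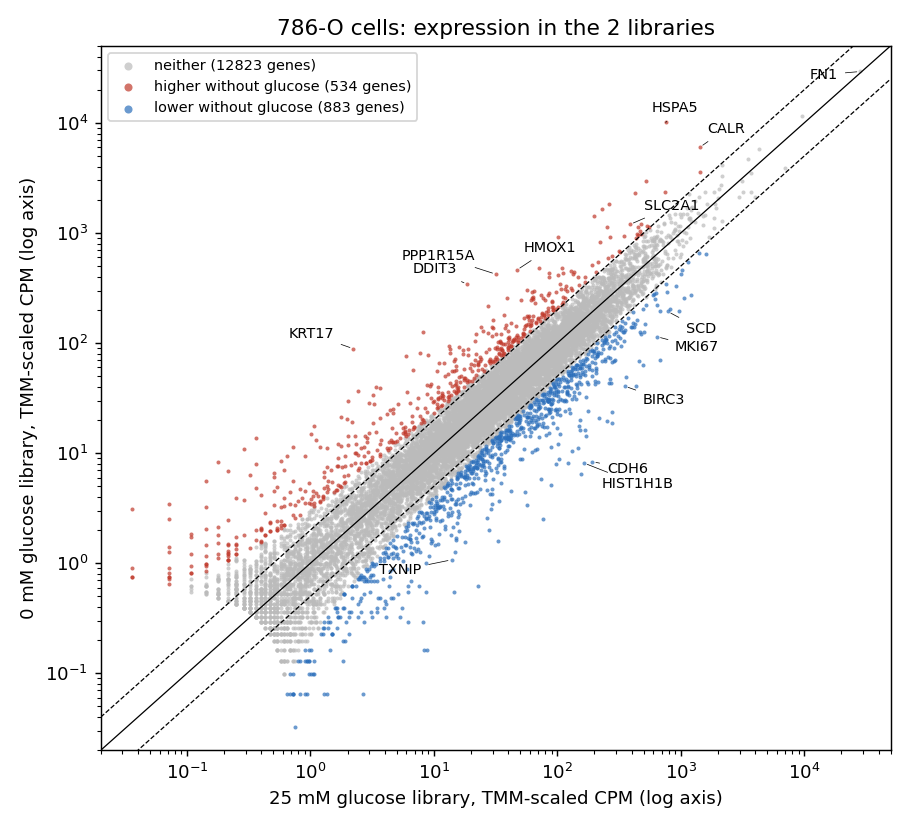
TMM-scaled CPM of each measured gene with a count in both libraries, with 25 mM glucose on the horizontal log axis and 0 mM glucose on the vertical log axis. Each point is 1 gene, the solid line marks equal values, the dashed lines mark 2-fold differences, red points are the genes higher without glucose by the rule of size (534 in all) and blue points the genes lower (883), and HSPA5 lies far above and CDH6 far below the line of equal values.

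In hg19 coordinates, HSPA5 lies on chromosome 9 from 127997127 to 128003666 on the minus strand, and DDIT3 on chromosome 12 from 57910371 to 57914300 on the minus strand. SLC2A1 lies on chromosome 1 from 43391046 to 43424847 on the minus strand, and TXNIP on the same chromosome from 145438462 to 145442628 on the plus strand. MKI67 lies on chromosome 10 from 129894925 to 129924468 on the minus strand, and CDH6 on chromosome 5 from 31193796 to 31325237 on the plus strand. Values rest on the counts of each gene model as the tables give them, and whether reads in introns were counted is not given.

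Genes of ER protein folding and of the integrated stress response were higher without glucose as groups. Of 29 measured ER chaperones and ER-associated degradation genes, 19 were higher and 0 lower, with a median log2 ratio of 1.55, at percentile 100 of the matched random lists. Besides HSPA5, they included PDIA4, a protein disulfide isomerase (264 to 1830 CPM, 2.79), DNAJB9, an HSPA5 cochaperone (13.2 to 94.5 CPM, 2.84), DERL3 (0.898 to 9.50 CPM, 3.40) and CALR, calreticulin (1427 to 6004 CPM, 2.07). Of 23 integrated stress response genes, 12 were higher and 0 lower (median 1.18, percentile 100), led by DDIT3 (log2 ratio 4.20), PPP1R15A, the GADD34 phosphatase subunit (3.73), ATF3 (3.40) and NDRG1 (2.84). ATF4, whose product is controlled largely at translation, had 222 and 300 CPM (0.44), within 2-fold. The ATF4 targets ASNS (0.30) and CHAC1 (-0.19) were also within 2-fold.

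Amino acid genes did not stand apart from the random lists as groups. Of 14 genes of serine, glycine, asparagine and proline synthesis, 1 was higher (GOT1, 1.23) and 1 lower (SHMT1, -1.30), with a median of 0.12 at percentile 71.0. The 18 cytosolic aminoacyl-tRNA synthetases had a median of 0.21 at percentile 80.5, with 1 gene past the rule, WARS (1.44). Of 14 amino acid transporters, SLC3A2, the heavy chain of the CD98 transporters (228 to 1662 CPM, 7.28-fold), and its partner SLC7A5 (2.30-fold) were higher and the glutamate transporter SLC1A3 (-1.41) was lower, with a median of 0.27 at percentile 87.2. This median lay above random lists matched also on length and GC content, at percentile 98.31, or 98.59 with the list's own genes left out of the draw.

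Of 23 measured genes of glycolysis and glucose uptake, 3 were higher and 3 lower without glucose. The glucose transporters SLC2A1 (388 to 1195 CPM, 3.08-fold, interval 3.01 to 3.15) and SLC2A3 (2.63-fold) and hexokinase HK2 (34.9 to 120 CPM, 3.45-fold) were higher, and the lactate exporter SLC16A3 (189 to 67.4 CPM, -1.49), LDHA (-1.30) and PFKFB3 (-1.26) were lower, the last 2 named after their values were seen. The median of the list was -0.43, at percentile 0.10 and below the random lists. Their mean lay inside the range of random lists, at percentile 8.11. Of 6 measured MondoA and ChREBP genes and targets, 1 was lower, TXNIP (-3.69), and the TXNIP paralog ARRDC4 had 3.20 and 3.81 CPM (0.25). The median of this list was -0.15 at percentile 28.6 and turned to 0.09 with genes of at least 1 count, and the mean of its members lay below the random lists at percentile 1.89. None of 7 pentose phosphate genes and none of 12 genes of gluconeogenesis, anaplerosis and glutamine use passed the rule, with medians of 0.04 (percentile 53.9, and -0.01 with scaling by total counts) and 0.08 (percentile 64.8).

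The hexosamine and N-glycan precursor list, which supplies sugars for protein glycosylation, had a median of 0.51 over 31 genes at percentile 100. UAP1 (1.33) and ALG5 (1.32) were higher by the rule and GFPT2 (-1.21) was lower. Hypoxia and HIF targets had a median of 0.61 over 24 genes at percentile 99.98, with 6 higher and 1 lower. EPAS1, the HIF-2 alpha subunit active in these cells, had 134 and 422 CPM (1.65), and ADM, adrenomedullin, had 36.8 and 181 CPM (2.30). VEGFA had 321 and 503 CPM (0.65), within 2-fold, and the lower gene was CA12 (-1.26), named after its value was seen. NDRG1 is a member of both this list and the stress response list.

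Redox, autophagy and p53-linked lists were above the random lists. Of 23 NRF2 targets and glutathione synthesis genes, 7 were higher and 1 lower (median 0.56, percentile 99.99). HMOX1, heme oxygenase 1, had 47.0 and 461 CPM (3.29, interval 3.21 to 3.38), and AKR1C1 (2.24), OSGIN1 (2.11) and the ferritin heavy chain FTH1 (1.96) were higher, where AKR1C1 and FTH1 have near-identical copies or pseudogenes and are uncertain. Of 34 autophagy and lysosome genes, 7 were higher and 1 lower (median 0.60, percentile 100). The autophagy receptor SQSTM1 had 269 and 924 CPM (1.78), MAP1LC3B, an LC3 protein of the autophagosome membrane, 13.0 and 52.6 CPM (2.02), and the gene below the bound was TFEB (-1.62). Of 21 p53-linked genes, 4 were higher and 0 lower (median 0.39, percentile 99.46), namely GADD45A (2.36), GDF15 (2.14), CDKN1A, the cell cycle inhibitor p21 (1.83), and PLK3 (1.47). GDF15, CDKN1A and SESN2 are also members of the integrated stress response list, so the p53-linked list is not a separate signal. The 25 apoptosis regulators had no member past the rule and a median of -0.02 at percentile 39.3, which was 0.02 with upper-quartile scaling and 0.06 with genes of at least 1 count.

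Of 18 cytosolic heat shock proteins, 4 were higher and 0 lower, with a median of 0.33 at percentile 95.7, inside the random range, and a mean above it. They were HSPA1A (4.48), HSPA1B (2.44), CRYAB (2.57) and DNAJB1 (1.81), and the near-identical HSPA1A and HSPA1B share reads and are uncertain as single genes. Immediate-early genes were mixed, with 6 of 25 higher, among them FOS (1.18 to 11.3 CPM, 3.25), FOSB (2.12) and CTGF (1.97), and 2 lower, among them NR4A3 (-2.23). Their median was 0.22 at percentile 91.9, inside the range, and their mean lay just above it at percentile 97.53.

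Lipid synthesis genes were lower without glucose. Of 12 fatty acid synthesis and desaturation genes, 6 were lower and 0 higher, with a median of -1.11 at percentile 0.01. SCD, the stearoyl-CoA desaturase, was 4.04-fold lower (782 to 194 CPM), FADS2 3.48-fold, the transcription factor gene SREBF1 3.45-fold and FASN 2.44-fold. Of 23 cholesterol synthesis genes, 4 were lower and 0 higher, with a median of -0.58 at percentile 0.02. Among them was HMGCS1, the cytosolic HMG-CoA synthase (262 to 117 CPM, -1.16). The 17 fatty acid oxidation genes and PPAR targets had a median of 0.28 at percentile 93.8, inside the range, with ANGPTL4 (2.21) and the lipid droplet protein PLIN2 (1.09) higher. The 40 nuclear-encoded respiratory chain and ATP synthase genes had a median of 0.11 at percentile 83.0 and no member past the rule.

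Proliferation genes were lower without glucose in most measured members. Of 31 mitosis and G2/M genes, 30 were lower, with a median of -1.88 (interval of the median -1.99 to -1.74) at percentile 0. ASPM was 6.57-fold lower, KIF20A 6.06-fold and CCNA2, cyclin A2, 4.82-fold. Of 33 DNA replication and S phase genes, 23 were lower and 0 higher, with a median of -1.41 at percentile 0, among them E2F2 (-3.21), MCM10 (-2.13) and TK1 (-1.90). The 18 replication-dependent histones, which package newly made DNA and whose mRNAs mostly lack a poly(A) tail, had 17 lower and a median of -2.64 at percentile 0. HIST1H1B, a linker histone, had 164 and 8.13 CPM (-4.34), and HIST1H3A had 32.8 and 1.59 CPM (-4.36). Single histone genes are uncertain because near-identical copies share reads.

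The medians of NF-kB-linked and interferon-stimulated genes lay below the random lists. Of 20 interferon-stimulated genes, 6 were lower and 0 higher (median -0.93, percentile 0.01), with OAS3, an antiviral oligoadenylate synthetase, at 137 and 33.2 CPM (-2.04) and IFI44L at 3.45 and 0.683 CPM (-2.34). Of 19 NF-kB-linked genes, 5 were lower and 1 higher (median -0.44, percentile 0.575). The interval of this median, -1.62 to 0.47, spanned 0, so the list was mixed. The chemokine gene CCL2 had 6.18 and 0.293 CPM (-4.40), the apoptosis inhibitor BIRC3 352 and 40.6 CPM (-3.11), CSF2 -2.05 and CSF1 -2.04 on the log2 scale, and the higher gene was IL11 (1.35), named after its value was seen.

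Ribosomal protein genes were higher without glucose as a group, by less than 2-fold for most members. The 74 cytosolic ribosomal proteins had a median of 0.63 (interval of the median 0.57 to 0.69) at percentile 100, with RPL37A (1.96) and RPL21 (1.13) past the rule. Their gene models are short, and in all measured genes the median log2 ratio was 0.31 in the shortest of 10 classes by length and -0.21 in the longest, with a Spearman correlation of -0.217 across genes. Random lists matched on length and GC content had a median of 0.35, against 0.65 for the 71 ribosomal protein genes with a GC value. The 30 ribosome biogenesis genes had a median of 0.32 at percentile 99.45 and 1 lower gene, UBTF, a factor of ribosomal RNA transcription (-1.13). The list of nuclear noncoding RNAs, fixed as a check of RNA quality, also differed between the libraries, with 5 of 9 measured genes higher and 0 lower without glucose (median 1.10, percentile 100). Genes of snoRNAs, scaRNAs and microRNAs took 5.83% of the counts with glucose and 7.99% without (95% Wilson intervals 5.818 to 5.836% and 7.977 to 7.996%), so the RNA make-up of the libraries differed along with the gene groups described here. With these small RNA genes left out, 550 genes were higher and 858 lower. GAS5, a snoRNA host transcript, had 759 counts with glucose and 6710 without, 8.01-fold more after scaling, and C7orf40 (2.03), SNHG12 (1.90) and SNHG1 (1.48) are hosts as well. MALAT1 had 9549 and 11467 CPM (0.26). Host genes hold small RNAs in their introns, and the use of strand is not given, so that reads from overlapping genes on the other strand cannot be told apart.

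**Figure D2:**
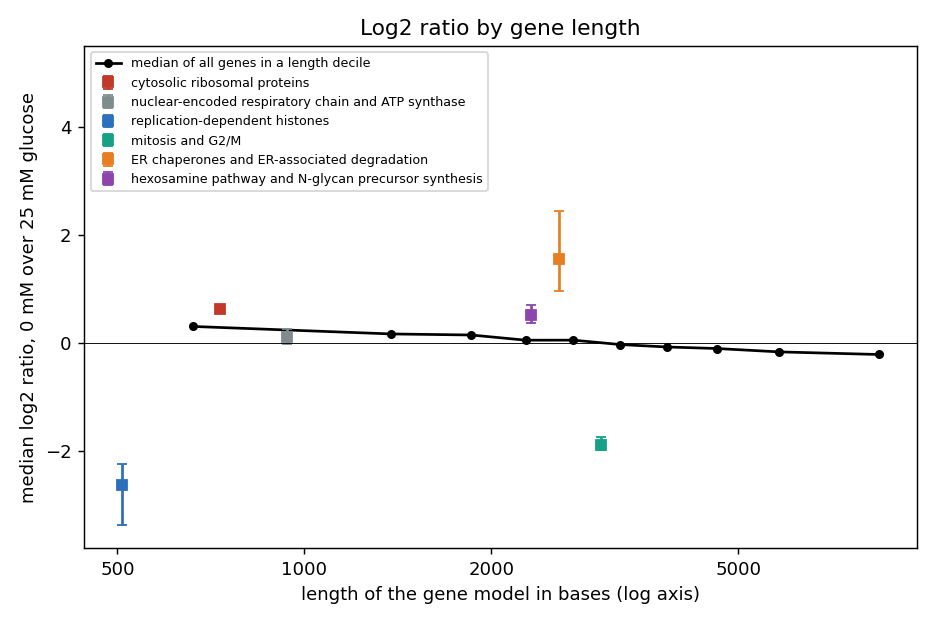
Median log2 ratio, 0 mM over 25 mM glucose, on the vertical axis against the median length of the gene model in bases on the horizontal log axis, for 10 equal classes of the measured genes by length (black line) and for 6 gene lists (squares, with the 95% binomial interval of the median). The line runs from 0.31 to -0.21, and the ribosomal proteins (0.63) and ER chaperones (1.55) lie above it while histones (-2.64) and mitosis genes (-1.88) lie below it.

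Renal epithelial markers had a median of -0.16 over 18 genes at percentile 17.9, inside the range, and a mean below it at percentile 1.32. Of these 3 were lower, among them CDH6 (-4.52) and the transcription factor gene LHX1 (-2.53), and VIM was within 2-fold (0.42). The 25 extracellular matrix and adhesion genes had a median of -0.28 at percentile 3.13, with the collagenase MMP1 (2.51) higher and LUM (-1.70) lower. Of the markers of other cell types, most leukocyte and endothelial ones were not measured, while 10 of 12 fibroblast markers were. Of leukocyte markers 3 were measured, LCP1 at 253 and 320 CPM, CD68 at 10.7 and 25.6 CPM (1.26) and CD14 under 1 CPM in both libraries, and of endothelial markers 4, with log2 ratios from -2.14 to -0.95, none past the rule, at 8 to 32 counts per library. The 10 fibroblast markers had a median of -0.47 at percentile 11.5, with LUM the only member past the rule, and 0 erythroid and 0 mitochondrial-genome genes were measured. The 18 reference genes had a median of 0.18 at percentile 69.4, with GAPDH at -0.09, ACTB at -0.74 and PPIB, an ER cyclophilin, the only member past the rule (1.36).

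**Figure D3:**
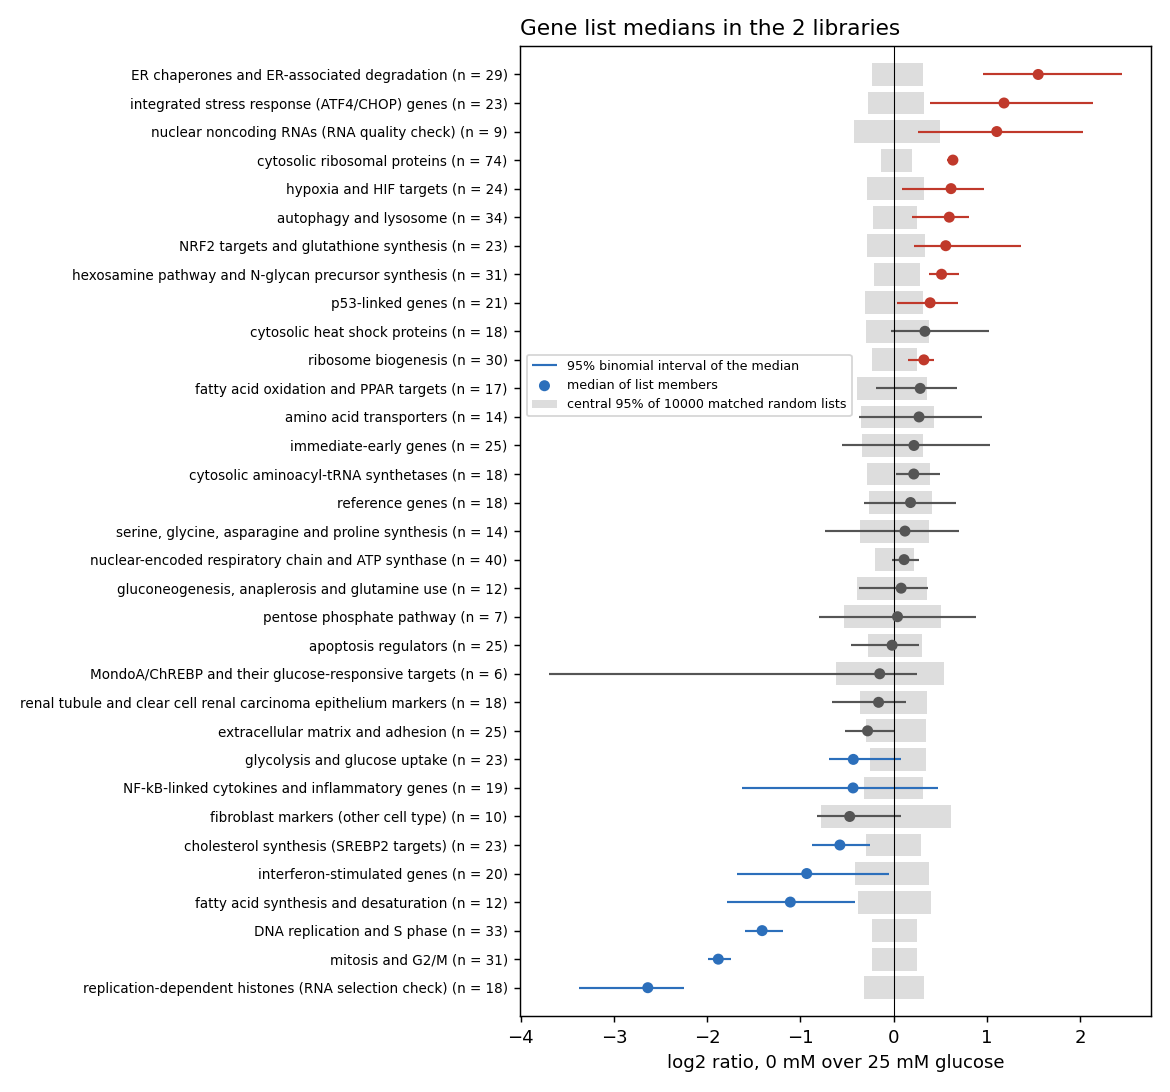
Median log2 ratio, 0 mM over 25 mM glucose, of the 33 gene lists with at least 5 measured members (points), with the 95% binomial interval of the median (lines) and the central 95% of 10000 matched random lists (grey bars). Red lists (10) lie above and blue lists (8) below their grey bars, from 1.55 for ER chaperones to -2.64 for replication-dependent histones.

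Of the 33 lists set against random lists, 10 lay above and 8 below the central range and 15 inside it, where 1.65 would be outside by chance if genes were independent. Lists share members and their genes vary together, so these counts describe the 2 libraries and cannot separate glucose from any other difference between 2 cultures.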

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

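With 1 library per group, no replicate could be left out. No paired analysis was possible because each group held 1 library. All settings chosen beforehand were run, and those on small RNA genes, gene length and GC content were chosen after seeing the data. The number of higher and lower genes depended on the size asked for. It was 1045 and 1515 with the ratio itself past 2-fold, 1451 and 1800 with the interval past 1.5-fold, and 122 and 147 with the interval past 4-fold, against 534 and 883, which follows from how each rule was built. Under the other scalings, count minimums, thinning, small RNA and length settings the counts stayed between 457 and 584 higher and between 793 and 972 lower. With the trend of length removed, 463 and 773 were the same genes. The median log2 ratio of all genes was -0.0413 with total counts, 2.26e-05 with size factors and 0.0523 with the upper quartile, against 0.0146, as each scaling fixes it. Of 166 named genes none changed the sign of a call, FN1, which passed neither bound, turned from 0.04 to -0.02 with total counts, and 35, 6 and 19 moved beyond their counting interval under these scalings. With 1 CPM added to both libraries, which by its construction draws weakly expressed genes towards 0, 29 moved beyond their interval and 25 ratios moved by over 1.5 times, among them HSPA6 (7.69 to 4.54), ATP6V0D2 (5.24 to 3.20), CCL2 (-4.40 to -2.47), MMP3 (5.26 to 3.44) and HSPA1A (4.48 to 2.73). Between 18 and 21 lists lay outside the random range. Glycolysis was inside it with the mean of members (percentile 8.11), while heat shock proteins and immediate-early genes were above it and the MondoA and renal lists below it. Endothelial markers were below it with at least 1 count (percentile 0.25). A gene with 20 counts needs a difference far past 2-fold to be called, so lower differences in such genes were not detectable at this depth.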

Other observations

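Beyond the lists, gene families were looked through after the values were seen. Of 16 measured keratin genes, structural proteins of epithelia, 5 were higher and 0 lower without glucose, with KRT17 at 2.23 and 88.8 CPM, KRT34 at 1.97 and 20.6 CPM (log2 ratio 3.38) and KRT16, KRT33B and KRT81 at lower levels. Keratin genes have close paralogs and pseudogenes, which leaves single members uncertain. Of 13 matrix metalloproteinase genes, MMP1, MMP3 and MMP10 were higher and 0 were lower. The ADAMTS secreted proteases went both ways. ADAMTS1 had 102 and 911 CPM (3.16), ADAMTS5 70.6 and 482 CPM (2.77) and ADAMTS6 16.1 and 92.4 CPM (2.52), while ADAMTS9 (-1.21), ADAMTS10 (-2.03) and ADAMTS12 (-1.27) were lower, out of 13 measured.

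Several single genes outside the lists differed strongly, again chosen after their values were seen. Lower without glucose were TGM2, transglutaminase 2 (498 to 63.3 CPM, -2.97), VCAM1, an adhesion molecule induced by cytokines (959 to 197 CPM, -2.29), TNFAIP2 (271 to 43.5 CPM, -2.64) and TNF (15.4 to 2.31 CPM, -2.74). The tight junction gene CLDN2 had 244 counts with glucose and 5 without (-5.75, interval -7.39 to -4.51). Higher were LCN2, the iron-binding lipocalin NGAL (3.41 to 39.6 CPM, 3.54), and SAT1, the polyamine acetyltransferase (64.3 to 299 CPM, 2.21). H1F0, a linker histone gene expressed outside S phase, was also higher (12.4 to 50.3 CPM, 2.02), against the lower replication-dependent histones.

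Of the tests below, those on RNA without a poly(A) tail, on reads shared between histone genes and on other differences between the cultures were chosen only after the result was seen. The matching of random lists on length and GC content was also chosen after seeing the data. The first pattern was the higher ER chaperones. Random lists matched on expression, gene length and GC content all had a lower median (percentile 100), which argues against a length or GC bias. The 21 members outside the 100 most counted genes had a median of 1.51, also at percentile 100. The shift was thus not confined to the most counted genes. With 19 of 29 members higher by the rule, this outcome was set in advance and is no separate evidence. A secretory pathway list of 36 other genes, of ER translocation and vesicle transport, was written before its values were seen. Its median was 0.14 at percentile 83.5, with 1 gene higher by the rule, SSR4 (1.27), and 0 lower. The pattern thus did not extend to this mixed list as a group. A response of the ER to loss of glucose for glycosylation may explain the pattern as a hypothesis, which 1 library per group leaves open.

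The second pattern was the lower histone, replication and mitosis genes. A library that retained less RNA without a poly(A) tail could have lower small nucleolar RNAs. The 274 measured snoRNA, scaRNA, RMRP and RPPH1 genes had a median of 0.454705, with 254 above 0, so they were not lower as a group. However, the shortest class of measured genes by length also had a median of 0.31. Small RNAs also lie in introns of host transcripts, several of which were higher, and host reads could add to their counts. The value therefore cannot decide whether less such RNA was retained. Reads moved between near-identical histone genes would lower some copies and raise others, whereas 58 of 63 measured cluster members were lower and 0 higher, and the summed counts of all 73 were 6.77-fold lower (log2 ratio -2.7595). This sum follows from its members and is no separate evidence that histone transcripts were fewer. A difference between the cultures other than glucose, such as their density, cannot be told apart from glucose with 1 library per group. Fewer cycling cells without glucose is a candidate explanation, which was not tested apart from that difference.

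The third pattern was the higher ribosomal protein and snoRNA host transcripts. A higher yield of short transcripts could raise both, and part of the ribosomal protein shift goes with length. However, the ribosomal proteins were at percentile 100 of random lists matched on expression, length and GC content. This argues against length as the whole cause, but the length classes of the matching were coarse, so differences in length within a class remain. Their mRNAs and those of several translation factors carry a 5' terminal oligopyrimidine tract. The 20 non-ribosomal genes of this class, listed before their values were seen, had a median of 0.47 at percentile 99.75 with 19 above 0. Against lists matched also on length and GC content, the 19 with a GC value were at percentile 98.8. The upper bound of that random range was 0.44, so the margin was small. Both values go with a shared change of this class. Many snoRNA host transcripts are degraded by nonsense-mediated decay, and 10 further hosts had a median of 0.83 at percentile 100, with 4 higher, among them SNHG8 (2.02). Against lists matched also on length and GC content, the 9 with a GC value were at percentile 99.97 (random range -0.14 to 0.61). This argues against length as the whole cause for these hosts, with the same limit of coarse length classes. Less decay could also raise the transcripts of 7 decay factors, which had a median of -0.16 at percentile 27.17 with 2 above 0. The random range for these 7 genes was -0.52 to 0.47, so a small rise could be missed. Transcript levels of the factors also do not measure decay itself. The values therefore cannot decide on less decay as the cause for the hosts.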
